A study of Mus musculus with 8 samples.

How the data were processed

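Messenger RNA was measured in Treg and Teff cells sorted from the spleens of WT and KO mice at day 7 of EAE, 4 groups of 2 libraries. Per the labels' protocols, RNA was extracted with TRIzol, polyadenylated RNA was selected with oligo(dT) beads, cDNA was made with random hexamers and amplified by PCR, and 50-base single-end reads were made on a DNBSEQ instrument. The labels name no step that marks the RNA strand and no molecular identifiers, so reads of overlapping and antisense genes cannot be told apart and PCR copies could not be told from separate molecules. Each library was mapped to its group by its cell type and genotype labels.

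Per the submitters' processing notes, the authors used Trim Galore 0.4.4, Salmon 0.14.1, R 4.0.3 and DESeq2 1.28.1 with the mouse build mm10; how transcripts were summed to genes and which genes were left out is not given in the sources used here. The authors deposited 1 table of 18438 genes with 1 signal column per library, a normalized read number that is not whole. In each library 1 read was worth between 0.981 and 1.03 for the commonest step, and 28.7% to 29.5% of the positive values were whole multiples of that step (tolerance 0.02), so whole reads could not be recovered and no count test was run. The deposited table also gives the authors' log2 fold changes of KO over WT in each cell type and their adjusted p-values, which are used only where the text names the authors' deposited table. Row numbers in that table run to 21784, and 3346 of these numbers do not occur in the table as used here, for a reason its labels do not give. Library sums ranged from 17504097 to 18751258. Divided by the commonest step, they put the reads behind them at 17795471 to 18595518, an estimate because most values are not whole multiples of it. The 10 strongest genes took 6.63% to 8.57% of a library and mitochondrial genes 5.22% to 7.33%. Depth was thus nearly even. Precision rests on 2 libraries per group, and whether deeper sequencing would add more was not tested.

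The design chosen before the data were examined assumed counts and named, for a table without counts, the test used here. Values were tested as log2(value + 1) with limma 3.58.1 (trend and robust empirical Bayes shrinkage) in R 4.3.3, with 1 coefficient per group over all 8 libraries, which leaves 4 residual degrees of freedom. Genes with a value of at least 10 in at least 2 libraries were tested, 13358 in all. P-values were adjusted by Benjamini-Hochberg within each of 5 contrasts (KO against WT in Treg, KO against WT in Teff, the difference between these effects, and Treg against Teff in WT and in KO) and called at 0.05. Gene symbols came from the file and coordinates from the GENCODE annotation (release M21) of GRCm38, the assembly also called mm10; all gene identifiers were found there, 97.2% with the same version. Coordinates are of whole genes, exons and introns together. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

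Of 32 gene lists fixed before the data were examined, the 29 with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01, again with the correlation estimated from the data, and with fry. Fry asks whether a list's genes move one way on balance and does not compare them with other genes. List p-values were adjusted over the lists of a contrast. Counts of called members are given over all genes and adjusted over the list alone. Fry called 75 of 145 pairs of a list and a contrast, 64 of them among the 72 that camera called at the preset correlation. For KO against WT in Treg it kept 8 of camera's 11 calls. It did not call interferon response, oxidative phosphorylation, or T cell activation and chemokine genes there (fry adjusted p = 0.0610, 0.0706 and 0.162). With the estimated correlation, 4 of camera's list calls held, all for Treg against Teff in WT (Treg core, naive and resting, Th1 and NK cell). Calls were lost even where the estimate lay below the preset 0.01. For Th1 genes in KO against WT Teff it was -0.0326, and for XBP1 target and ER folding genes in Treg 0.00207. Stronger correlation between genes is therefore not the reason for these losses.

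Genes named in the text followed a rule fixed before the data were examined. They were Ern1, Xbp1, Foxp3 and Il2ra, and up to 4 members per list with the smallest p. Added were, per contrast, the 12 higher and 12 lower genes of largest change that passed, had no overlap between the libraries compared and reached a mean of 5 CPM (values scaled to a library sum of 1000000) in the higher group (6 per direction for the difference of effects). A gene named for 1 contrast may be described in the others. Unnamed or predicted genes, pseudogenes marked as such by symbol, and immunoglobulin and T cell receptor segments were left out of these additions. The rule also took every member of the lists of UPR sensors and sex-linked genes, but the text describes no sex-linked gene and only some of the sensors. A gene outside the rule is named with that said, or only as a copy or neighbour of a named one, or as a marker or list member whose levels a test in the closing section rests on.

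The test was tried on simulated negative binomial values with the mean of each gene in each cell type, a spread following the trend of the fitted residuals, and changes planted in the KO libraries. In Treg it recovered 50.7% of 67 genes changed 1.5-fold, 70.2% of 67 changed 2-fold and 84.8% of 66 changed 4-fold, with 7 false calls among 13158 unchanged genes; in Teff the shares were 46.3%, 67.2% and 87.9%, with 12 false calls. With changes planted in KO Treg alone, the shares for the difference of effects were 28.4%, 68.7% and 87.9%, with 5 false calls. The simulated spread varied less from gene to gene than the fit found in the data, so these shares and false calls may be too favourable. Alternatives were other scalings (upper quartile, library totals), filters, pseudocounts and threshold, replicate blocks, fitting only the groups compared, leaving out each library in turn and the list tests above. Added after seeing the data were quantile normalization, limma without robust shrinkage and a crossed replicate block.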

Results

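RNA was sequenced from T cells sorted from the spleens of C57BL/6 mice at day 7 of experimental autoimmune encephalomyelitis (EAE), a mouse model of multiple sclerosis induced here with MOG, a myelin protein. Regulatory T cells (Treg, sorted as CD4+ CD25hi YFP+) and effector T cells (Teff, sorted as CD4+ CD25- YFP-) came from wild-type (WT) mice and from mice labelled as lacking IRE1a (KO). IRE1a, encoded by Ern1, is a sensor of misfolded protein in the endoplasmic reticulum (ER). The 4 groups held 2 libraries each, 8 in all. The deposited values were normalized read numbers for 18438 genes. They summed to between 17504097 and 18751258 per library, and between 16324 and 16642 genes had a value above 0. Values below are means of n = 2 libraries ± SD. Fold changes are on the log2(value + 1) scale, which understates the change of weakly expressed genes. No label said whether the 2 libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical.

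Libraries separated first by cell type and then by genotype. The first principal component held 56.6% of the variance and split Treg from Teff, and the second held 14.9% and split KO from WT. The 2 libraries of a group correlated at r between 0.982 and 0.985 across well expressed genes on the log2 scale, and no pair held identical values.

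The first question was whether the targeted gene differed between genotypes. Ern1 (chromosome 11, 106394650 to 106487852 of GRCm38) had 388 ± 15.7 in WT and 342 ± 23.3 in KO in Treg (SD, n = 2; log2 fold change -0.18, SE 0.10, adjusted p = 0.489). In Teff it had 587 ± 40.0 in WT and 455 ± 3.67 in KO (log2 fold change -0.37, SE 0.10, adjusted p = 0.0902). Both KO means lay below their WT means, and neither difference passed the test. The values cover whole genes and the labels do not say which part of Ern1 was removed, so transcripts of a disrupted allele can still be counted and the value is no check of the genotype labels. Which cells carry the deletion is not given either. Differences below are therefore between genotypes, and those in Teff need not come from loss of IRE1a in Teff. Xbp1, whose mRNA IRE1a splices, had 1625 ± 32.8 in WT and 1918 ± 115 in KO in Treg and 1323 ± 51.9 in WT and 1519 ± 195 in KO in Teff. It did not pass the test in either (adjusted p = 0.325 and 0.312). Gene-level values do not show splicing. Foxp3, the lineage factor of Treg, had 90.7 ± 2.19 in WT Treg and 114 ± 4.15 in KO Treg, was listed at 0 in both WT Teff libraries, and had 5.17 ± 4.41 in KO Teff. Il2ra, which encodes CD25 and so follows the sort, had 8978 ± 48.9 and 8793 ± 133 in WT and KO Treg against 639 ± 72.4 and 486 ± 71.6 in Teff.

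**Figure D1:**
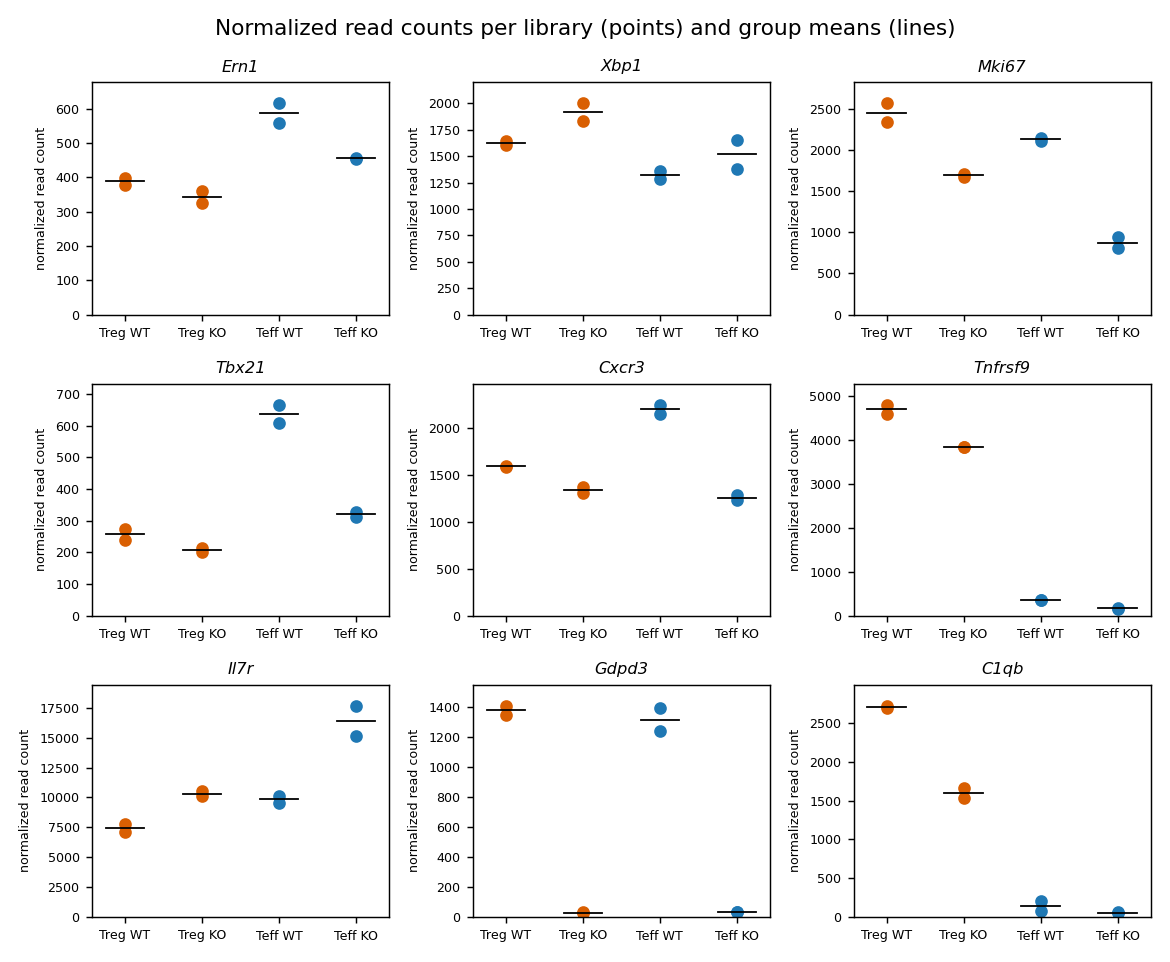
Normalized read numbers (vertical axes, each starting at 0) of 9 genes in the 4 groups. Each point is 1 library and each line the mean of a group's 2 libraries. Ern1 lay at 587 in WT Teff and 455 in KO Teff, Mki67 fell from 2129.7 to 874 in Teff, and Gdpd3 was low in both KO groups.

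The second comparison asked what differed between KO and WT Treg. KO Treg held more transcript of genes of naive and resting T cells and less of single activation and proliferation genes, while the Treg lineage list did not pass its test. S1pr1, the receptor that lets T cells leave lymphoid tissue, rose from 4647 ± 46.7 to 7045 ± 44.5 (SD, n = 2; log2 fold change 0.60, SE 0.05, adjusted p = 0.00155). Satb1 encodes a chromatin organizer of T cells and Il7r the receptor for a survival cytokine. They rose by 0.43 and 0.48 on the log2 scale (adjusted p = 0.0152 and 0.0480). In this list 4 of 17 tested members rose, or 11 adjusted over the list alone, with a median log2 fold change of 0.37 (camera adjusted p = 6.50e-11, adjusted p = 0.0664 with an estimated correlation). The calls of Satb1 and Il7r were lost when any single Treg library was left out, with adjusted p up to 0.141 and 0.255 over 20 alternatives. The Il7r call was also lost without either WT Teff library. That of S1pr1 held at 0.0260 or below. In total, 194 of 13358 tested genes passed limma's test (adjusted p below 0.05), 90 higher and 104 lower in KO, and 1964 had an unadjusted p below 0.05.

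Among proliferation genes in Treg, 2 of 34 tested members fell, or 6 adjusted over the list alone, with a median of -0.28 (camera adjusted p = 3.07e-06, adjusted p = 0.183 with an estimated correlation). The called members were Mki67, a marker of cycling cells (log2 fold change -0.53, adjusted p = 0.0408), and Rrm2, a subunit of ribonucleotide reductase (log2 fold change -0.68, adjusted p = 0.0463). The Rrm2 call did not hold with upper-quartile scaling, library totals or quantile normalization. Of 22 tested T cell activation genes 1 fell, or 6 adjusted over the list alone: Irf4, a transcription factor induced by T cell receptor signals (log2 fold change -0.56, adjusted p = 0.0429; camera adjusted p = 0.0402, adjusted p = 0.470 with an estimated correlation). Irf4 was also the 1 called member of the effector Treg list, in which 3 of 22 fell adjusted over the list alone (camera adjusted p = 0.352). Interferon response genes had a median of -0.22, and 1 of 33 tested members fell, or 11 adjusted over the list alone (camera adjusted p = 2.63e-05, adjusted p = 0.312 with an estimated correlation). The called gene was Tap1, a peptide transporter of antigen presentation, at -0.28 (adjusted p = 0.0397). Glycolysis genes had a median of -0.18, and 1 of 19 tested members fell, or 2 adjusted over the list alone (camera adjusted p = 0.000132, adjusted p = 0.154 with an estimated correlation). The called gene was Hif1a, a regulator of glycolysis, at -0.40 (adjusted p = 0.0248). All 5 single-gene calls were lost when any single Treg library was left out. Those of Mki67 and Tap1 were also lost without either WT Teff library, that of Irf4 without either KO Teff library, and that of Rrm2 without any single Teff library. Over 20 alternatives the adjusted p reached 0.225 for Mki67, 0.246 for Rrm2, 0.224 for Irf4, 0.231 for Tap1 and 0.174 for Hif1a.

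The Treg core list, which holds genes of Treg identity, did not pass as a group in KO Treg (camera adjusted p = 0.119). Its median was -0.10, with 5 of 23 tested members above 0. In this list 1 member was called higher, or 2 adjusted over the list alone, and 0 were called lower, or 3 adjusted over the list alone. The riser was Gpr83, a receptor found on Treg, which went from 1287 ± 3.29 to 2486 ± 17.6 (SD, n = 2; log2 fold change 0.95, SE 0.09, adjusted p = 0.00291). Th1 genes, which mark interferon-gamma-producing helper cells, had no called member of 15, 5 lower adjusted over the list alone, and a median of -0.26 (camera adjusted p = 0.000906, adjusted p = 0.154 with an estimated correlation). Cholesterol synthesis had none of 21 called, 3 lower adjusted over the list alone and a median of -0.12 (camera adjusted p = 0.00565, adjusted p = 0.154 with an estimated correlation). Oxidative phosphorylation had 0 of 33 by either adjustment and a median of -0.12 (camera adjusted p = 0.00287, adjusted p = 0.337 with an estimated correlation). The lists of Th17 cells (0 of 17 called), Th2 cells (0 of 6), follicular helper T cells (Tfh, 1 of 16 lower) and IL-2 and STAT5 signalling (0 of 17) did not pass, with camera adjusted p = 0.956, 0.570, 0.531 and 0.381. Adjusted over the list alone the first 3 had 0, 0 and 1 lower genes, and IL-2 and STAT5 had 2 higher and 4 lower. Of 16 apoptosis genes 2 rose, or 3 with 1 lower adjusted over the list alone (camera adjusted p = 0.394): Bcl2l11, which encodes the death-promoting protein BIM (log2 fold change 0.95, adjusted p = 0.00626), and Casp4 (log2 fold change 0.65, adjusted p = 0.0429). The Bcl2l11 call was lost without either WT Treg library (adjusted p up to 0.0748 over the alternatives) and the Casp4 call without any single Treg library or either KO Teff library (up to 0.230).

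No single gene of the response that IRE1a controls was called in Treg, though its lists lay slightly lower in KO. Of 51 tested XBP1 target and ER folding genes none was called by either adjustment, 14 had a fold change above 0, and their median was -0.11 (camera adjusted p = 0.00809, adjusted p = 0.154 with an estimated correlation). Calr, an ER chaperone, had 14191 ± 121 in WT and 12811 ± 582 in KO (adjusted p = 0.229), and Pdia6, a disulfide isomerase, 367 ± 7.02 in WT and 213 ± 62.8 in KO (adjusted p = 0.121). Of 10 tested targets of regulated IRE1-dependent decay (RIDD), mRNAs that IRE1a can cut, none was called, 1 fell adjusted over the list alone, all 10 lay below 0, and the median was -0.25 (camera adjusted p = 0.00206, adjusted p = 0.244 with an estimated correlation). Loss of cutting alone would raise these mRNAs, so their lower values run opposite to it. The PERK-ATF4 list, a parallel ER stress branch, had 0 of 27 called by either adjustment, and the UPR sensor list 0 of 6 by either (camera adjusted p = 0.674 and 0.361).

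The strongest single differences in Treg were in genes outside the fixed lists, and most were also seen in Teff. Kcnf1, a potassium channel subunit (chromosome 12, 17172100 to 17176888), rose from 1.47 ± 0.694 to 407 ± 2.37 (log2 fold change 7.39, SE 0.41, adjusted p = 0.000285). The sialyltransferase genes St6galnac1 and St6galnac2, neighbours on chromosome 11, which also holds Ern1, rose by 5.29 and 4.00, and Mid1, a ubiquitin ligase gene on chromosome X, by 2.29. Gdpd3, a phosphodiesterase-family gene (chromosome 7, 126766334 to 126775649), fell from 1375 ± 42.4 to 28.0 ± 1.98 (log2 fold change -5.57, SE 0.14, adjusted p = 1.14e-05), and Eps8l1 changed by -3.53 and Lad1 by -4.80. Rps3a3, a copy of the ribosomal protein gene Rps3a1, had 3769 ± 162 in WT and 35.4 ± 4.20 in KO, and the class I histocompatibility genes H2-Bl and H2-Q1 rose by 3.97 and 3.47. Reads of Rps3a3, H2-Bl and H2-Q1 can be shared with near-identical copies, so their values are uncertain. All the gene calls of this paragraph kept an adjusted p under 0.05 under each of the 20 alternatives.

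The count in Treg depended on single libraries. It was 44 without WT replicate 1, 51 without WT replicate 2, 67 without KO replicate 1 and 72 without KO replicate 2. The authors' deposited table called 453 genes (194 higher, 259 lower), of which 189 were among the 194 here, all with the same sign. The balance of directions moved as well, to 30 higher and 14 lower without WT replicate 1 and 31 and 20 without WT replicate 2. It was 103 and 96 with library totals, and 78 and 152 when only the 2 Treg groups were fitted, with 133 genes shared.

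The third comparison asked the same of Teff. KO Teff held less transcript of genes of proliferation, T helper 1 and follicular helper function, activation and suppressive effector function, and more of genes of resting T cells. In all, 924 genes passed limma's test (adjusted p below 0.05), 678 lower and 246 higher, of which 294 and 79 differed by over 2-fold. Mki67 fell from 2129.7 ± 28.7 to 874 ± 91.7 (SD, n = 2; log2 fold change -1.29, SE 0.09, adjusted p = 0.000844). Rrm2 fell from 420.3 ± 11.8 to 154 ± 3.26, and Top2a, the topoisomerase of dividing cells, from 1064 ± 139 to 524 ± 59.5 (adjusted p = 0.00149 and 0.00570). Among proliferation genes 16 of 34 tested members fell, or 26 adjusted over the list alone, with a median of -0.86 (camera adjusted p = 3.51e-15, adjusted p = 0.0797 with an estimated correlation). Mcm6, part of the DNA replication helicase, fell by 0.73 on the log2 scale (adjusted p = 0.00482).

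Among Th1 genes 10 of 15 tested members fell, or 11 adjusted over the list alone, with a median of -0.67 (camera adjusted p = 4.59e-08, adjusted p = 0.0797 with an estimated correlation). Tbx21, which encodes the Th1 factor T-bet, fell from 638 ± 40.2 to 321 ± 11.2 (SD, n = 2; log2 fold change -0.99, SE 0.12, adjusted p = 0.00582). Cxcr3, a chemokine receptor of Th1 cells, fell from 2202 ± 73.1 to 1262 ± 34.8, and the cytokine gene Tnf from 797 ± 18.5 to 489 ± 19.8 (adjusted p = 0.00144 and 0.00647). Among Tfh genes 11 of 16 tested members fell, or 12 adjusted over the list alone, with a median of -0.70 (camera adjusted p = 4.26e-10, adjusted p = 0.0797 with an estimated correlation). The transcription factor gene Tox changed by -0.72, the secreted BMP antagonist gene Sostdc1 by -1.80 and Pdcd1, which encodes the inhibitory receptor PD-1, by -0.67 (adjusted p = 0.00142, 0.00143 and 0.00511). Among Th17 genes 4 of 17 tested members fell, or 5 adjusted over the list alone (camera adjusted p = 0.00454, adjusted p = 0.246 with an estimated correlation), led by the protease gene Furin at -0.72 (adjusted p = 0.00189). Of 6 tested Th2 genes 2 fell, or 3 adjusted over the list alone (camera adjusted p = 0.00547, adjusted p = 0.156 with an estimated correlation), with Pparg, a lipid-sensing nuclear receptor gene, at -3.24 (adjusted p = 0.00372).

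Genes best known from Treg, most of which Teff express at a lower level, also fell in KO Teff. Among effector Treg genes 15 of 22 tested members fell, or 20 adjusted over the list alone, with a median of -0.76 (camera adjusted p = 1.97e-14, adjusted p = 0.0959 with an estimated correlation). Gzmb, which encodes the cytotoxic protease granzyme B, fell from 261 ± 30.6 to 95.3 ± 12.5 (SD, n = 2; log2 fold change -1.44, SE 0.14, adjusted p = 0.00302). Irf4 fell from 1622 ± 215 to 888 ± 10.2 (adjusted p = 0.00438). In the Treg core list 12 of 23 tested members fell, or 14 adjusted over the list alone, and 2 rose, or 2 adjusted over the list alone (camera adjusted p = 8.06e-07, adjusted p = 0.122 with an estimated correlation). The costimulatory receptor genes Tnfrsf9 (4-1BB) and Tnfrsf4 (OX40) went from 359 ± 1.37 to 166 ± 9.06 and from 1347 ± 20.0 to 739.8 ± 86.7 (adjusted p = 0.000768 and 0.00246). The 2 higher members were Gpr83 (0.88, adjusted p = 0.00279, which reached 0.0564 when only the 2 groups compared were fitted) and Foxp3. Foxp3 stood near the floor, at 0 in both WT Teff libraries (adjusted p = 0.0419). Its call was lost in 10 of 19 alternatives, including those without either WT Teff library, without KO Teff replicate 2 and without any single Treg library, where adjusted p reached 0.146. T cell activation and chemokine genes had 10 of 22 lower, or 14 lower and 1 higher adjusted over the list alone (camera adjusted p = 2.33e-08, adjusted p = 0.0952 with an estimated correlation), Itgb1 among them (log2 fold change -0.67, adjusted p = 0.00438). IL-2 and STAT5 genes had 5 of 17 lower, or 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000382, adjusted p = 0.0959 with an estimated correlation). These lists share members, such as Tnfrsf9 and Irf4, so their counts are not independent.

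Genes of resting T cells were higher in KO Teff. In this list 5 of 17 tested members rose, or 10 adjusted over the list alone, where 1 fell, and the median was 0.22 (camera adjusted p = 1.31e-06, adjusted p = 0.0797 with an estimated correlation). Il7r rose by 0.74 on the log2 scale (SE 0.08, adjusted p = 0.00493, at most 0.0355 over 20 alternatives). Interferon response genes had a median of -0.29, and 10 of 33 tested members fell, or 14 adjusted over the list alone (camera adjusted p = 8.06e-07, adjusted p = 0.139 with an estimated correlation). Oas1a and Isg20, an antiviral synthetase and an exonuclease gene, changed by -0.71 and -0.84 (adjusted p = 0.00585 and 0.00838), and with only the 2 groups compared in the fit these rose to 0.0520 and 0.0615. In metabolism, 2 of 19 glycolysis genes fell, or 2 adjusted over the list alone (camera adjusted p = 0.00181, adjusted p = 0.0959 with an estimated correlation), with Hif1a at -0.55 (adjusted p = 0.00360). Of 21 cholesterol synthesis genes 2 fell, or 4 adjusted over the list alone (camera adjusted p = 0.00155, adjusted p = 0.0959 with an estimated correlation). Oxidative phosphorylation had 0 of 33 called by either adjustment (median -0.04, camera adjusted p = 0.976).

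As in Treg, the ER stress lists held few called genes in Teff. Of 51 XBP1 target and ER folding genes 1 fell, or 0 adjusted over the list alone, and the median was -0.09 (camera adjusted p = 0.0241, adjusted p = 0.111 with an estimated correlation). That gene was Wfs1, which encodes an ER membrane protein (log2 fold change -1.05, adjusted p = 0.0376), and its call was lost when any 1 of the 8 libraries was left out (adjusted p up to 0.179 over the alternatives). RIDD targets had 1 of 10 lower, or 4 adjusted over the list alone, PERK-ATF4 genes 2 of 27 by both adjustments, and UPR sensors 1 of 6, or 3 adjusted over the list alone, with camera adjusted p = 0.0862, 0.245 and 0.0862. Asns, the asparagine synthetase gene, and the stress factor gene Atf3 changed by -2.40 and -1.24, and Atf6, the sensor of another ER stress branch, by -0.76 (adjusted p = 0.0114, 0.0209 and 0.0128). Adjusted p for these 3 reached 0.0646, 0.111 and 0.0676 over the alternatives. The Asns call was lost without WT Teff replicate 2, the Atf6 call without KO Teff replicate 2, and the Atf3 call without either of these or WT Teff replicate 1. In the apoptosis list 2 of 16 rose and 2 fell by both adjustments (camera adjusted p = 0.976).

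**Figure D2:**
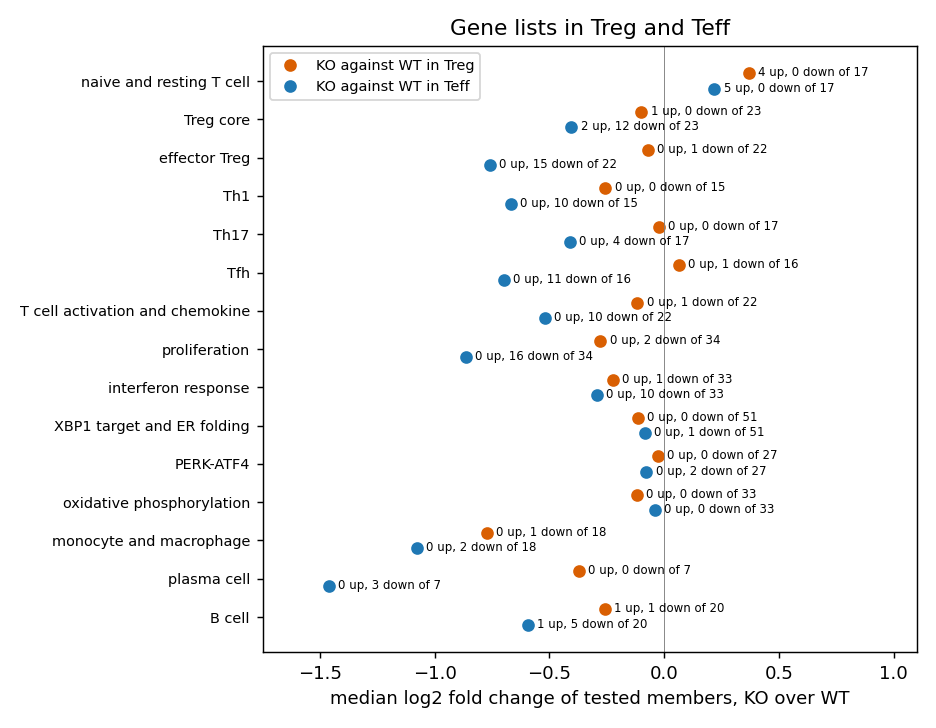
Median log2 fold change of KO over WT (horizontal axis) of the tested members of 15 gene lists, in Treg (orange) and Teff (blue), with the number of members called higher and lower beside each point. The proliferation list had a median of -0.86 in Teff and -0.28 in Treg, and the naive and resting list lay above 0 in both.

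Lists of other cell types moved with genotype too. Monocyte and macrophage genes had a median of -1.08 in KO Teff, where 2 of 18 tested members fell, or 10 adjusted over the list alone (camera adjusted p = 8.87e-07, adjusted p = 0.111 with an estimated correlation). In KO Treg their median was -0.77, and 1 of 18 tested members fell, or 6 adjusted over the list alone (camera adjusted p = 5.18e-07, adjusted p = 0.183 with an estimated correlation). Summed over the list, the level was 1816 and 1883 CPM in the WT Treg libraries and 1165 and 1140 CPM in the KO Treg libraries. Whether this drop shares in the other lists that lay lower in KO Treg was not tested. C1qb, a complement gene of macrophages, had 2709 ± 21.5 in WT Treg, 1596 ± 92.2 in KO Treg, 137 ± 94.3 in WT Teff and 52.6 ± 7.34 in KO Teff, and did not pass the test in either cell type. Plasma cell genes had a median of -1.46 in KO Teff, and 3 of 7 tested members fell, or 4 adjusted over the list alone (camera adjusted p = 0.000872, adjusted p = 0.0959 with an estimated correlation). B cell genes had 5 of 20 lower and 1 higher, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.00775, adjusted p = 0.0959 with an estimated correlation). The immunoglobulin light chain gene Igkc had 761 ± 132 in WT and 272 ± 42.5 in KO (adjusted p = 0.00438). Dendritic cell genes had 2 of 11 lower and 1 higher, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.0130, adjusted p = 0.363 with an estimated correlation). In Treg, plasma cell (0 of 7 by either adjustment), B cell (1 higher and 1 lower of 20, or 3 and 3 adjusted over the list alone) and dendritic cell (0 of 11 by either) lists did not pass (camera adjusted p = 0.389, 0.848 and 0.0726). Neutrophil, erythroid, and stroma and endothelium lists had no called gene by either adjustment (camera adjusted p = 0.300, 0.204 and 0.670 in Treg and 0.0875, 0.153 and 0.368 in Teff). The NK cell list did not pass either (0.956 and 0.496), with 1 of 9 genes higher in each, or 2 higher and 2 lower in Treg and 1 higher in Teff adjusted over the list alone. The CD4 T cell identity list had no called gene in Treg and 1 of 12 lower in Teff, or 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.848 and 0.152). No gene of the CD8 T cell, platelet and sex-linked lists, which had under 5 tested members, was called in either cell type.

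The Teff count also depended on which libraries were fitted. It was 347 without KO Teff replicate 2, 353 and 477 without WT Teff replicate 2 and 1, and 572 and 578 without WT Treg replicate 2 and 1, and 210 when only the 2 Teff groups were fitted. The authors' deposited table called 1131 genes (327 higher, 804 lower), of which 830 were among the 924, all with the same sign.

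The fourth comparison asked whether the KO effect was the same in both cell types. Of the genes called in Treg, 52 of 90 higher and 76 of 104 lower genes were called the same way in Teff, against 1.66 and 5.28 for independent lists. The 2 contrasts share no library but one fit, in which a gene with a small pooled spread is more easily called in both, so 1.66 and 5.28 are not what no shared effect would give. In all, 129 genes were called in both cell types, 1 of them in opposite directions, 795 in Teff alone and 65 in Treg alone. Across the 13358 tested genes the 2 log2 fold changes correlated at Pearson's r = 0.367 and Spearman's rho = 0.341, and at r = 0.661 and rho = 0.688 across the 989 genes called in either. Genes are not independent replicates, so no p is given, and genes called in either were chosen for their size. The genes shared included Kcnf1, St6galnac2, H2-Bl and Mid1 on the higher side, where Teff rose by 4.70, 5.52, 4.08 and 2.07, and Gdpd3, Eps8l1 and Rps3a3 on the lower side, where Teff changed by -5.35, -3.84 and -6.94. The Treg-associated Gpr83 rose and the heat shock gene Hspa1b fell in both (-1.10 in Treg and -1.06 in Teff). Of these genes, Kcnf1, St6galnac2, H2-Bl and Hspa1b each lie within 1 Mb of another gene called the same way in both cell types. So do St6galnac1, Lad1, H2-Q1, Hif1a and Sostdc1, while Mid1, Gdpd3, Eps8l1, Rps3a3 and Gpr83 do not.

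**Figure D3:**
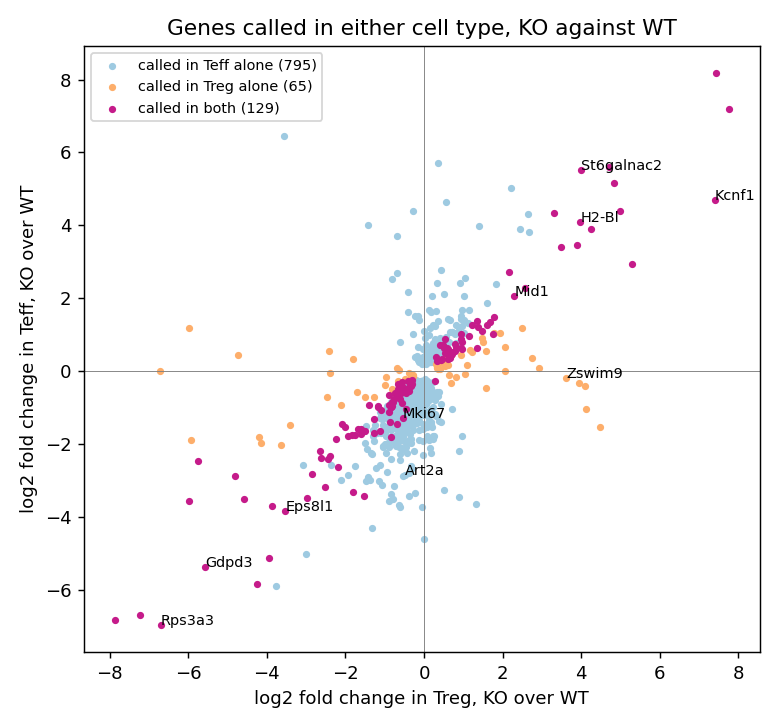
Log2 fold change of KO over WT in Treg (horizontal axis) against that in Teff (vertical axis) for the 989 genes called in at least 1 cell type, 1 point per gene. Of these, 129 were called in both, 795 in Teff alone and 65 in Treg alone. All but 1 of the genes called in both have the same sign on both axes, and most genes called in Teff alone lie below 0 on the vertical axis.

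Testing the difference between the effects directly, 3 genes passed (limma, adjusted p below 0.05; 1384 had an unadjusted p below 0.05), all with a higher effect in Treg. Art2a, a gene of the ADP-ribosyltransferase family, had 659 ± 16.1 in WT and 91.2 ± 5.01 in KO in Teff (log2 fold change -2.84, SE 0.11, adjusted p = 7.40e-05). In WT and KO Treg it had 393 ± 9.81 and 279 ± 16.2, a difference of 2.34 (SE 0.16, adjusted p = 0.00889). Zswim9, a zinc finger gene, rose in Treg from 21.1 ± 1.56 to 269 ± 0.284 and had 241 ± 50.7 in WT and 210.1 ± 0.0149 in KO in Teff, a difference of 3.79 (SE 0.26, adjusted p = 0.00889). The third was the T cell receptor segment Trav7d-6, which lies outside the naming rule and was chosen after its values were seen. It was listed at 0 in both WT Treg libraries and had 21.6 ± 5.55 in KO Treg, against 82.0 ± 2.37 and 27.8 ± 1.43 in WT and KO Teff (adjusted p = 0.0247). The count was 0 without WT Treg replicate 1 and 1 without either KO Treg library, none of which was among these 3, and Art2a and Zswim9 reached an adjusted p of 0.125. Art2a lost its call without any single Treg library or either WT Teff library, and Zswim9 without WT Treg replicate 1, either KO Treg library or either KO Teff library. Trav7d-6 lost its call whichever of the 8 libraries was left out (adjusted p up to 0.162) and with each replicate block, and all 3 lost theirs with a replicate block within genotype.

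As groups, 12 of the 29 tested lists differed between the effects, 11 of them lower in Teff relative to Treg, and 0 of the 12 held with an estimated correlation. Among these, the Tfh list had a median difference of 0.65 and the effector Treg list one of 0.58. Proliferation and Th1 genes had medians of 0.51 and 0.39. Camera's adjusted p for these 4 was 1.25e-14, 8.87e-15, 9.57e-08 and 0.000215. All 4 calls were lost at adjusted p = 0.135 with an estimated correlation. No single member of these 4 lists passed over all genes tested, and 11, 14, 7 and 7 were higher adjusted over the list alone, with 1 Th1 gene lower. Mki67, for instance, differed by 0.75 (adjusted p = 0.124), Cxcr3 by 0.55 (adjusted p = 0.124) and Tox by 0.66 (adjusted p = 0.0719). The naive and resting list did not differ (camera adjusted p = 0.371), nor did the XBP1 target and ER folding list (0.899).

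The last comparisons set Treg against Teff within each genotype. In WT, 3357 genes passed limma's test, 1806 higher and 1551 lower in Treg, and in KO 3597, 2100 higher and 1497 lower. Of these, 1424 were higher and 1024 lower in both genotypes. The split depended on the scaling: it was 2037 higher and 1278 lower in WT and 2481 and 1159 in KO with library totals, and 1645 and 1835 in WT and 1843 and 1921 in KO with quantile normalization. All 23 tested Treg core genes were higher in Treg in WT and in KO by either adjustment (medians 2.07 and 2.50; camera adjusted p = 1.47e-24 and 2.41e-24, adjusted p = 0.0435 and 0.0590 with an estimated correlation). In WT, Il2ra differed by 3.81 (SE 0.11, adjusted p = 5.75e-06), Tnfrsf9 by 3.71 and Ctla4, an inhibitory receptor gene, by 2.07. Lrrc32, which encodes the latent TGF-beta receptor GARP, had 3192 ± 169 in WT Treg and 64.4 ± 48.3 in WT Teff, and Klrg1, a receptor of terminally differentiated T cells, 1081 ± 29.4 and 28.7 ± 6.32 (SD, n = 2).

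Genes of naive T cells and of Th1 and Th17 cells were lower in Treg than in Teff. Of naive and resting genes 15 and 13 of 17, or 16 and 15 adjusted over the list alone, were lower in WT and in KO (camera adjusted p = 4.08e-12 and 3.70e-11, adjusted p = 0.0392 and 0.0590 with an estimated correlation). Of Th1 genes 12 and 11 of 15, or 12 and 11 adjusted over the list alone, were lower (camera adjusted p = 2.01e-08 and 0.000189, adjusted p = 0.0392 and 0.0902 with an estimated correlation), and of Th17 genes 11 and 12 of 17, or 12 and 12 adjusted over the list alone (camera adjusted p = 8.36e-07 and 1.001e-04, adjusted p = 0.129 and 0.173 with an estimated correlation). Of Th2 genes 3 and 4 of 6, or 3 and 4 adjusted over the list alone, were higher and 1 was lower in each, and the list passed as higher in KO alone (camera adjusted p = 0.116 and 0.0179, adjusted p = 0.432 and 0.239 with an estimated correlation). Tfh genes had 9 of 16 lower and 2 higher in WT and 6 lower and 7 higher in KO, or 11 and 2 and then 6 and 7 adjusted over the list alone (camera adjusted p = 0.00217 and 0.830, adjusted p = 0.207 and 0.891 with an estimated correlation). CD4 T cell identity genes were lower in Treg, with 7 and 8 of 12, or 9 and 8 adjusted over the list alone (camera adjusted p = 1.43e-05 and 0.00110, adjusted p = 0.0561 and 0.138 with an estimated correlation). NK cell genes were lower as well, with 9 and 7 of 9, or 9 and 8 adjusted over the list alone (camera adjusted p = 6.85e-08 and 1.37e-06, adjusted p = 0.0392 and 0.0590 with an estimated correlation). In WT, Igfbp4, a gene of naive T cells, differed by -3.11, Cxcr6, a chemokine receptor gene, by -3.39, the interleukin gene Il17a by -4.10 and Klrk1, an NK cell receptor gene, by -3.86. Siglech, a gene of plasmacytoid dendritic cells, had 206 ± 14.1 in WT Teff and 4.11 ± 1.65 in WT Treg. Dendritic cell genes were lower in Treg (6 and 6 of 11, or 8 and 8 adjusted over the list alone; camera adjusted p = 0.00820 and 0.0120, adjusted p = 0.432 and 0.469 with an estimated correlation). Of plasma cell genes 4 and 2 of 7, or 4 and 2 adjusted over the list alone, were lower, and the list passed in WT alone (camera adjusted p = 0.0165 and 0.458, adjusted p = 0.207 and 0.690 with an estimated correlation).

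Higher in Treg, beside the Treg genes, were monocyte and macrophage genes (16 and 15 of 18, or 16 and 16 adjusted over the list alone; camera adjusted p = 1.33e-08 and 2.25e-08, adjusted p = 0.129 and 0.138 with an estimated correlation). Hmox1, the heme oxygenase gene, had 5518 ± 293 in WT Treg and 386 ± 205 in WT Teff, and Csf1r, the macrophage growth factor receptor gene, 3564 ± 129 and 207 ± 132. Erythroid genes were higher as well (5 and 6 of 9, or 7 and 7 adjusted over the list alone; camera adjusted p = 0.000777 and 0.00112, adjusted p = 0.142 and 0.169 with an estimated correlation). Proliferation genes had 4 of 34 higher and 1 lower in WT (camera adjusted p = 0.274), and in KO 16 of 34 higher (camera adjusted p = 6.81e-06, adjusted p = 0.169 with an estimated correlation). Adjusted over the list alone 3 and 17 were higher. Ern1 itself was lower in Treg than in Teff in WT (log2 fold change -0.59, SE 0.10, adjusted p = 0.00550). The WT count fell to 2212 and 2086 without WT Treg replicate 1 and 2, and the KO count to 2351 and 2365 without KO Treg replicate 1 and 2.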

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

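Each result here differs between Treg and Teff in the size of the KO effect by a test of that difference. Of the tests that weigh explanations, the one on chromosomal position was set before its result was seen, and those on Treg cells and on macrophage RNA were chosen after the values they rest on had been seen.

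For 3 genes the KO effect in Treg exceeded that in Teff on the log2 scale, by 2.34 for Art2a, 3.79 for Zswim9 and 6.00 for Trav7d-6. The last is a fitted value and no fold, since Trav7d-6 was listed at 0 in WT Treg. Trav7d-6 lost its call whichever library was left out, Art2a without 6 of the 8 and Zswim9 without 5, and all 3 with a replicate block within genotype. Median differences of lists were 0.48 for Treg core, 0.58 for effector Treg, 0.39 for Th1, 0.54 for Th17, 0.33 for Th2 and 0.65 for Tfh. They were 0.51 for proliferation, 0.20 for IL-2 and STAT5, 0.30 for T cell activation and chemokine, 0.60 for B cell, 1.09 for plasma cell and -0.0849 for oxidative phosphorylation. With an estimated correlation none of the 12 list differences passed, with adjusted p between 0.135 and 0.363.

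The pattern most open to follow-up is the lower level of proliferation, activation and effector genes in KO Teff. The 601 genes lower in KO Teff and not called in Treg did not crowd together on the chromosomes. Of them 58.7% had another within 1 Mb, against a mean of 56.6% in 10000 random sets of tested genes, 1784 of which reached it. Leaving out genes called in Treg removed the shared calls, where a local effect of another strain's genome could show in both cell types. The test therefore does not decide whether such stretches act on genes of this pattern, and effects on genes elsewhere stay open as well. More Treg cells in the WT Teff sorts would dilute Th1 genes that Treg express less, yet 9 Th1 genes with a lower mean in WT Treg than in WT Teff (8 of them past the test) fell in KO Teff. This bears on such Th1 genes alone. For genes that Treg express more than Teff, such as Tnfrsf9, more Treg cells in the WT Teff sorts stay open. More macrophage RNA in the WT Teff sorts was weighed over the 102 tested genes of these lists. Of them, 97 had a lower mean in KO Teff. The measure was 11 macrophage markers chosen for a high level in WT Treg beside WT Teff, which summed to 24010 against 1644. Had such RNA supplied the difference, WT Treg would need to hold these genes at a median of 8.56 times their level there. Over pairs of a WT and a KO Teff library this was 4.68 to 62.4. For the group means, Tbx21 would need 8210 against 257 and Cxcr6 13360 against 106. Choosing markers this way can raise that need, which was not recomputed over the whole macrophage list. That list stood at 1816 and 1883 CPM in WT Treg and 369 and 300 CPM in WT Teff. The values argue against macrophage RNA as the whole cause only if the 11 markers stand for the same macrophages in both sorts. A weaker or later response of Teff in KO mice, which the design names only as genotype, is a hypothesis that stays open and untested, as does a different mix of naive and activated cells within the CD25- gate.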

How the results depend on the processing

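Alternatives added after seeing the data were quantile normalization, limma without robust shrinkage and the crossed replicate block; the others were planned. Counts not given here stayed within 1.5 times. The balance of higher and lower genes turned with the scaling. Treg against Teff in KO went from 2100 and 1497 to 1843 and 1921 with quantile normalization, and in WT from 1806 and 1551 to 1645 and 1835. Treg KO against WT went from 90 and 104 to 103 and 96 with library totals. The number of genes called in Treg KO against WT, 194, became 114 with a replicate block, 430 at an adjusted p below 0.10, and 44 to 192 with 1 library left out. In Teff, 924 became 210 when only the 2 groups were fitted, 1497 at 0.10, and 347 to 642 with 1 library left out; the block gave 688. The 3 genes whose effect differed became 5 with library totals only, 5 with no filter, 6 with a pseudocount of 5, 0 with a block within genotype, 26 at 0.10, and 0 to 3 with 1 library left out; the block gave 2. Treg against Teff gave 2086 to 3315 in WT and 2351 to 3572 in KO with 1 library left out. The looser threshold of 0.10 admits more genes by construction. The causes of the other changes were not tested, and fitting only the 2 groups raised the Treg count to 230. A sole library of a group is taken to vary like the other groups.

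With the correlation estimated, list calls went from 11 to 0 (Treg KO), 19 to 0 (Teff KO), 12 to 0 (difference of effects), 15 to 4 (Treg against Teff in WT) and 15 to 0 (in KO), and from 72 to 4 in all. Leaving out 1 library gave 68 to 75 in all. The correlation of KO effects across genes, 0.367, was 0.473 over genes with at least 1 CPM in 4 libraries, 0.654 over genes with a mean of at least 10 CPM, and 0.309 to 0.354 with 1 library left out. Among 395 named gene and contrast pairs, 7287 of 7877 comparisons kept direction and side of the threshold, 583 no longer passed, 5 newly passed and 2 changed direction without passing.

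Deviations of same-numbered libraries correlated at -0.103 between the Treg groups and -0.116 between the Teff groups, and at -0.0247 to 0.0561 otherwise, so no pairing by number was seen. A crossed block, replicate 1 with replicate 2, called 129 genes in Treg, 753 in Teff and 2 for the difference. No scaling moved the median of all genes by over 0.1 on the log2 scale. DESeq2 size factors and its test, limma-voom and edgeR were not run, since the values are not counts.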

Other observations

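All tests of explanations in this part were chosen after the results they bear on had been seen. Ribosomal protein transcripts, not tested as a group, took 5.06% of both WT Treg libraries and 5.10% and 5.11% of the KO Treg libraries. They took 6.64% and 6.99% of the WT Teff libraries, and 8.10% and 8.02% of the KO Teff libraries. The early stress response list, which can also move with handling, had 5 of 18 members lower in KO Teff, or 7 adjusted over the list alone (camera adjusted p = 0.00430, adjusted p = 0.363 with an estimated correlation). In KO Treg 1 was lower, or 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.119). Hspa1b, an inducible heat shock protein gene, went from 732 ± 0.507 to 341 ± 0.460 in Treg and from 703 ± 63.2 to 335 ± 6.22 in Teff (SD, n = 2), and it lies among the shared calls of the H2 region. The NK cell list gave 1 called gene by genotype, Prf1, which encodes perforin. It rose in KO Treg from 80.1 ± 8.94 to 157 ± 18.6 and in KO Teff from 439 ± 4.07 to 766 ± 12.6, with adjusted p = 0.0248 and 0.0198. These reached 0.164 and 0.0947 over the alternatives: the Treg call was lost without any single Treg library or either WT Teff library, and the Teff call without any single Teff library.

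Ighm, an immunoglobulin heavy chain gene, stood at 11088 ± 10.2 in WT Treg and 16818 ± 233 in KO Treg, and at 5298 ± 228 and 6712 ± 430.1 in WT and KO Teff. Of other B cell genes, Cd79b had 242 ± 16.2 in WT Treg and 33.7 ± 0.0945 in WT Teff, and Ighd 272 ± 19.3 in KO Treg and 45.2 ± 3.21 in KO Teff. Cd79a and Ms4a1, chosen after their values were seen, had 40.2 ± 1.40 and 22.5 ± 0.529 in WT Treg. Foxp3 was low beside the gene for CD25, at 90.7 ± 2.19 in WT Treg against 8978 ± 48.9 for Il2ra.

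The genes called the same way in both cell types lay close together on the chromosomes, which a stretch of another strain's genome carried by the KO mice might produce: 42.2% had another within 1 Mb, a share that 0 of 10000 random sets of tested genes reached (mean 19.4%). It was 35.5% without chromosome 17, where 16 lay in the H2 region (33951999 to 36190287), and 28.3% when T cell receptor segments were also left out, reached by 3 and 94 random sets. The random sets were not matched for neighbouring members of a gene family, such as St6galnac2 and St6galnac1. Such neighbours may therefore add to the closeness without a foreign stretch. Groups of shared calls also lay on chromosome 11, which holds Ern1: Cd300ld and Fads6 at 114982274 to 115297663, and Cygb, St6galnac2 and St6galnac1 at 116645595 to 116775507. Further groups lay on chromosomes 1, 7, 10, 12 and 14. Whether the KO mice carry a foreign stretch around the targeted gene was not tested. Reads moving between copies could account for Rps3a3, since the sum of Rps3a1, Rps3a2 and Rps3a3 changed by only -0.0756 in Treg and 0.07 in Teff while Rps3a3 nearly vanished. It falls short for Rps18, whose sum with 3 named copies rose by 0.27 in Treg and 0.54 in Teff, although copies under other names were not summed. Pseudogenes made up 15.6% of the shared calls against 3.40% of the calls in Teff alone and 4.09% of tested genes, and an effect of IRE1a loss common to both cell types stays open for these genes.

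Macrophage markers were abundant in the Treg libraries: C1qa, chosen after its values were seen, had 2403 and 2422 in WT and 1451 and 1427 in KO. It did not pass the test (adjusted p = 0.608), whose spread is pooled over all groups, and in WT Teff it had 214.9 and 49.4. A candidate source is macrophages, or their RNA, in the Treg sorts: over 11 markers of the fixed list, chosen for a high level in WT Treg beside WT Teff, 1 factor per library took 88.8% of the variance over the 4 Treg libraries, a share that 0 of 10000 random gene sets of like level reached (median 8.16%). That factor largely follows genotype, because the 2 libraries of a group were nearly equal, so a change of these genes within Treg, set by genotype, stays open as well. A CD4 gate should remove most macrophages, and YFP is not explained by the labels.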
